A study of Oryza sativa with 9 samples.

How the data were processed

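Stem tissue RNA of 9 samples of the rice variety Kavya was measured on Affymetrix rice arrays: 3 uninfested controls, 3 with gall midge biotype GMB1 and 3 with biotype GMB4M. Per the labels' protocols, seedlings grew for 15 days in a glasshouse, infested samples pool 24, 48, 96 and 120 h, maggots were removed, RNA was taken with Trizol and a Qiagen column, and biotin label was added with the kit supplied for the arrays. The deposited values are probe set signal intensity on a linear scale, all above 0; per the submitters' processing notes they come from MAS5 and GCOS, whose versions and settings are not given in the sources used here. The deposited signal was not brought to one level per array: the mean after trimming 2% at each end ran from 194 (GMB4M replicate 1) to 304 (GMB4M replicate 3). No detection calls were used here. No pair of arrays was identical, and 0 value columns lacked a sample.

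Of 57381 probe sets, 123 array controls were left out, leaving 57258. The platform table pairs 22436 of these with 1 gene, 95 with several and 34727 with none, for 17905 genes; names came from the RefSeq table of assembly ASM3414082v1, in which all 17905 matched and 2457 had a name other than a LOC number. The array's genome build is not given in the sources used here, so no coordinates are printed. Probe sets above their own array's median in at least 3 of 9 arrays were kept (30410).

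Log2 of the deposited signal was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with trend), with 1 mean per group over all 9 arrays, and 3 comparisons: GMB1 against control, GMB4M against control and GMB4M against GMB1. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested probe sets of a comparison. Adjusted p-values of single genes in the text are limma's. Tables and figures were handled in Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.

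The groups, tests, alternatives, naming rule and subjects of 25 gene lists were set before the data were examined. The lists were to be drawn from gene descriptions, which the annotation lacks. They were therefore rewritten as patterns of gene symbols and aliases after the annotation was seen and before any test. They cover pathogenesis-related proteins, protease inhibitors, jasmonate, salicylate and ethylene genes, WRKY factors, resistance gene receptors, phenylpropanoid, flavonoid and diterpenoid phytoalexin synthesis, class III peroxidases, antioxidant enzymes, cell wall genes, photosynthesis, histones and cell cycle, KNOX genes, cytosolic ribosomal proteins, heat shock proteins, auxin, gibberellin and cytokinin, sugar and starch, nitrogen supply, lipid transfer with wax and cuticle, LEA proteins and dehydrins, and seed storage proteins. The heat shock list also holds heat stress transcription factor genes (HSF). The patterns match gene names only, and 2457 of 17905 genes had one other than a LOC number. Each list is therefore the named part of its subject. Lists with at least 5 tested genes (21) were tested with camera at a preset correlation of 0.01. Camera took 1 probe set per gene (the one with the highest mean, 16086 genes), with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and fry, which does not set a list against the other genes, were run beside it. Fry p-values are given unadjusted.

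Named genes follow a rule. Per comparison they are the 8 probe sets up and 8 down with the largest absolute log2 change among those called, without overlap between the 3 and 3 arrays, with a higher group mean above the 75th percentile and with exactly 1 gene that has a name other than a LOC number. The rule asked for an informative description, which the gene name replaced. Such a name was held by 49 of the 257 probe sets called in GMB1 against control. In GMB4M against control it was held by 84 of 436. Of every list with called members the 2 with the largest change were added. Where none passed, the 8 with the smallest p in each direction among those meeting the signal and gene name parts of the rule are named and said not to pass. Further called list members are named where a count of 7 or fewer is given; these were chosen after their values were seen. Where the mean of a named gene's dimmer group lay below the median of every array of that group, its change is given as a bound, with each dim array set to at least its median.

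Replicate numbers recur in all groups and the labels do not say what they share. Each array's deviation from its group mean was correlated with that of the same number in the other group. These correlations were 0.436, 0.266 and 0.148 for GMB1 against control and 0.367, 0.145 and 0.190 for GMB4M against control. All lie above 0.1, so replicate number was also fitted as a block in these comparisons, a pairing read from the data. Deviations within a group sum to 0, so an effect shared by the replicate 1 arrays alone would raise all 3 correlations. They therefore cannot show that numbers 2 and 3 pair. Outside its group, control replicate 3 was best matched by GMB1 replicate 2 (0.199), and 5 of 9 arrays by their own number. For GMB4M against GMB1 they were 0.450, 0.152 and 0.0972, and the numbers were not taken as pairs.

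Quality measures were compared between groups by exact permutation, whose smallest 2-sided p with 3 against 3 arrays is 0.1. Replicate 1 was set against replicates 2 and 3 over 27 arrangements, a contrast that was not among the tests set beforehand. Agreement of the responses was compared with 100 simulations of 2 unchanged groups against 1 shared control group, every array drawn on its own, so without replicate effects. The limma and camera steps were tested on simulated data made from each probe set's mean over all 9 arrays and its spread within the 3 groups. Every simulated value was drawn on its own. In the simulated GMB1 group 200 of 30410 probe sets were changed. Of these, 0% of 67 changed 1.5-fold, 1.49% of 67 changed 2-fold and 48.5% of 66 changed 4-fold were recovered. In this test 2 unchanged probe sets were called, the shifted list was found and 0 other lists were called. The simulated genes had no correlation with each other. The test therefore cannot show how often camera calls an unshifted list among correlated genes.

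Counts of called probe sets were recomputed under quantile normalization, median centring, an offset of 32 before the log, no filter, a filter at the 60th percentile, eBayes without trend, robust eBayes, arrayWeights, fits of only the groups compared, leaving out probe sets shared between genes (_x_at and _s_at), the replicate block and with each array left out in turn. Called lists were recomputed under quantile normalization, median centring, the offset, no filter, without shared probe sets, under the block, with the estimated correlation and with each array left out. The correlation of the responses was recomputed under both normalizations, the offset, both filters, the block and with each array left out. Leaving out an array leaves 2 in its group, whose spread is pooled with that of the other groups. A batch term for replicate 1, replicates 2 and 3 alone, median centring over the tested probe sets, and quantile normalization with either batch setting were chosen after seeing the data.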

Results

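RNA from stem meristematic tissue of the rice variety Kavya was hybridised to 9 Affymetrix rice arrays. The arrays fall into 3 groups of 3: uninfested control seedlings, seedlings infested with gall midge biotype GMB1 and seedlings infested with biotype GMB4M. The gall midge is a fly whose maggots feed at the growing point of the rice stem. Seedlings were 15 days old, and each infested sample pools material collected 24, 48, 96 and 120 h after infestation, with the maggots removed before extraction. The labels give no time for the controls, so the groups may also differ in harvest age. As background from outside the labels, Kavya carries the resistance gene Gm1, against which GMB1 is avirulent and GMB4M virulent. The labels do not say whether the 3 replicates of a group came from separate cultures of plants; where they did not, p-values measure only the spread between these samples, which may be technical.

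The value table held 57381 probe sets, 123 of them array controls, and 30410 passed the filter on signal. The number of arrays limits the precision. The trimmed mean signal was 264 ± 13 (SD, n = 3) in control, 242 ± 1.49 (SD, n = 3) in GMB1 and 255 ± 55.8 (SD, n = 3) in GMB4M, with the lowest array at 194 and the highest at 304, both GMB4M. Probe sets for 25S and 28S ribosomal RNA had a geometric mean signal of 182 ± 75.3 (SD, n = 3) in control, 71.5 ± 10.7 in GMB1 and 78.0 ± 42.9 in GMB4M. Every control array was above every infested array, and the 2-sided exact permutation p was 0.1 in both comparisons, the smallest that 3 against 3 arrays allow. The Bacillus spike controls were also higher in control, at 888 ± 177 (SD, n = 3), than in GMB1, at 530 ± 155, and GMB4M, at 560 ± 242, again with an exact p of 0.1. GMB1 also had an exact p of 0.1 for trimmed mean signal and hybridisation controls, both lower than in control. The same held for the share of tested probe sets above the array median, which was higher. In GMB4M the exact p for these was 0.9, 0.2 and 0.3.

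Replicate 1 of every group lay below replicates 2 and 3 in some measures of the arrays and not in others. The ratio of actin 3' to 5' signal was 4.63 in control replicate 1 against 16.4 and 9.33 in replicates 2 and 3, 3.89 against 11.9 and 10.4 in GMB1, and 3.21 against 6.50 and 10.3 in GMB4M. The ratio of Bacillus spike to hybridisation control signal was 0.507 against 0.725 and 0.618 in control, 0.285 against 0.544 and 0.540 in GMB1, and 0.307 against 0.535 and 0.527 in GMB4M. These ratios, the Bacillus spike signal, the median signal and the share of tested probe sets above the array median, 5 of 11 measures, had a 2-sided exact p of 0.037 over 27 arrangements, the smallest possible, and a Benjamini-Hochberg adjusted p of 0.081. The other measures had no such p: cyclophilin ratio 0.0741, trimmed mean signal 0.185, Magnaporthe controls 0.407, ribosomal RNA 0.556, GAPDH ratio 0.593 and hybridisation controls 0.815. Control replicate 1 correlated at 0.922 and 0.926 across probe sets with the other controls, which correlated at 0.979 with each other. Probe sets are not independent replicates. The contrast of replicate 1 was not among the tests set beforehand, and its p does not allow for the choice of that number. The Bacillus spike signal is also part of the Bacillus ratio, so the measures are not all separate. Replicate 1 was treated as a possible batch, and values from replicates 2 and 3 alone are given beside the pooled ones. Control replicate 1 was also closer to most infested arrays than to its own group. It correlated at 0.944, 0.925 and 0.936 with GMB1 replicates 1, 2 and 3, and at 0.941, 0.937 and 0.933 with those of GMB4M. Why it lay nearer to infested arrays was not tested. Replicate 1 has 1 array per group, so it allows a difference and no test.

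The first comparison, GMB1 against control, asks how Kavya tissue changed under the biotype it resists. Of 30410 probe sets, 257 passed an adjusted p of 0.05, 115 higher and 142 lower in GMB1 (44.7% higher). All 257 had no overlap between the 3 GMB1 and the 3 control arrays, which held for 22.4% of all tested probe sets and would by chance hold for 10%. The called log2 changes reached 4.12 and −4.92. The median over tested probe sets was −0.09; it became 0.02 after quantile normalization, with 60.3% of 673 calls higher, and 0.03 after median centring, with 55.2% of 449 higher. Changes of lists are therefore given as the list's median minus the median of all genes, unless stated otherwise. With replicate number as a block 1471 probe sets were called, and with replicates 2 and 3 alone 2503, of which 32.8% and 35.6% were higher; these kept 257 and 254 of the 257. Single arrays decided the count: without control replicates 1, 2 and 3 in turn it was 729, 51 and 31, and without GMB1 replicates 1, 2 and 3 it was 66, 74 and 163. In data simulated from the means and spreads of all 9 arrays, 0% of 67 probe sets changed 1.5-fold and 1.49% of 67 changed 2-fold were recovered. Of 66 changed 4-fold 48.5% were recovered, so many changes of these sizes would be missed.

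Under GMB1 the list with the lowest median was diterpenoid phytoalexin synthesis, the route to the momilactones and phytocassanes that rice makes against pathogens. All 12 tested genes were lower, by a list median of −2.10 relative to all genes (camera adjusted p 2.7e-11, but 0.122 with an estimated correlation between genes). Within replicate 1 the value was −2.16 and within replicates 2 and 3 it was −1.70. Over all probe sets 7 were called, and 8 adjusted over the list alone. The 7 were CPS2 and CPS4, which encode copalyl diphosphate synthases, KSL4 and KSL7, kaurene synthase-like enzymes, and the cytochrome P450 genes CYP99A2, CYP99A3 and CYP71Z7. On the log2 scale CYP71Z7 changed by −2.52 or further (fitted −2.97, SE 0.50, adjusted p 0.0199) and KSL4 by −2.15 or further (fitted −2.85, SE 0.57, adjusted p 0.0405); their mean GMB1 signals of 19.5 and 14.6 lay below the median of every GMB1 array, so only bounds are given. CPS2 changed by −2.80 (SE 0.54, adjusted p 0.0375) and CYP99A2 by −2.19 (SE 0.36, adjusted p 0.0199). CYP99A2 signal had a geometric mean of 336 in control and 73.7 in GMB1.

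Jasmonate synthesis and signalling genes fell in a part of the list. Of 35 tested, 27 were lower, 4 were called and 6 were called adjusted over the list alone, all lower (list median −0.23 relative to all genes, adjusted p 0.000131, but 0.684 with an estimated correlation; −0.32 within replicate 1, −0.16 within replicates 2 and 3). The chloroplast lipoxygenase gene CM-LOX1 changed by −3.07 (SE 0.31, adjusted p 0.00272), from a mean signal of 470 to 55.9. CM-LOX2 changed by −2.41 (SE 0.44, adjusted p 0.0292), the 12-oxophytodienoate reductase gene OPR-1 by −2.77 (SE 0.45, adjusted p 0.0180; its other probe set, at −1.82, was not called) and the allene oxide synthase gene AOS2 by −1.59 (SE 0.29, adjusted p 0.0302). WRKY transcription factors were lower in 6 of 6 tested genes, the named ones only (−0.57, adjusted p 0.0189, but 0.593 with an estimated correlation). Of these, 0 were called over all probe sets and 3 over the list alone. Within replicate 1 the shift was −0.13 and within replicates 2 and 3 it was −0.56. Without GMB1 replicate 2 the WRKY call ended, at an adjusted p of 0.14.

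Other genes that fell strongly were GLP2, a germin-like protein gene, at −3.42 (SE 0.38, adjusted p 0.00403; mean signal 623 to 58.3), cap2 at −2.79 (SE 0.54, adjusted p 0.0375) and CAD8A, of the cinnamyl alcohol dehydrogenase family, at −2.22 (SE 0.39, adjusted p 0.0244). NH1, the rice homologue of the salicylate regulator NPR1, fell by 1.16 (SE 0.22, adjusted p 0.0339), from a mean signal of 2218 to 994.

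The cell wall loosening and synthesis list was called higher under GMB1 at the preset correlation: 39 of 51 genes were higher, 1 was called and 3 over the list alone (0.52 relative to all genes, adjusted p 1.4e-07, but 0.593 with an estimated correlation; 0.39 within replicate 1, 0.56 within replicates 2 and 3). The called gene was EXLA4, an expansin-like gene, at 1.47 (SE 0.27, adjusted p 0.0304). LEA proteins and dehydrins, which accumulate in drying tissue, were higher in 8 of 8 genes (1.22, adjusted p 1.0e-05, but 0.36 with an estimated correlation; 0.87 within replicate 1, 1.48 within replicates 2 and 3). One array carried much of this: each gene set to its mean over 9 arrays, the list median was 2.16 in GMB1 replicate 3, against −0.18 and 0.02 in replicates 1 and 2. In this list rab25 was called, at 1.29 (SE 0.25, adjusted p 0.0375), and 3 genes were called over the list alone.

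Among the genes that met the naming rule, MEL1 rose most, by 3.16 (SE 0.47, adjusted p 0.0138), from a mean signal of 29.4 to 262; it encodes an Argonaute protein known from germ cells. MADS18, a MADS-box transcription factor gene of the APETALA1 and FRUITFULL group, rose by 2.63 (SE 0.30, adjusted p 0.00415; 257 to 1589). The plasma membrane aquaporin genes OsPIP2;4 and OsPIP1;3 rose by 2.49 (SE 0.30, adjusted p 0.00458) and 2.08 (SE 0.30, adjusted p 0.0129). Lsi6, a silicon channel gene of the aquaporin family, rose by 1.92 (SE 0.29, adjusted p 0.0138), RFS by 1.83 (SE 0.25) and the auxin response factor gene ARF16 (LOC4327785) by 1.81 (SE 0.30, adjusted p 0.0182). OsCASPL2B1 rose by 1.99 (SE 0.35) through 1 probe set, while its other probe sets gave −0.72 and 1.11 and were not called. Of the gibberellin and cytokinin list, which was not called, 2 genes were: the cytokinin oxidase gene CKX3 rose by at least 1.48 (fitted 2.29, SE 0.40, adjusted p 0.0244; mean signal 14.0, below the median of every control array, to 68.6) and the response regulator gene RR1 by 1.77 (SE 0.35, adjusted p 0.0384). OSH1, a KNOX gene of the shoot meristem, rose by 1.74 (SE 0.33, adjusted p 0.0369) on 1 probe set and by 1.16 on its other, which was not called (adjusted p 0.0537). The small heat shock protein gene HSP18.6 rose by 1.77 (SE 0.27, adjusted p 0.0143) and by 1.59 on its other probe set (adjusted p 0.0142), and the glutathione S-transferase gene GST-I by 1.27 (SE 0.26, adjusted p 0.0449).

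Of the 21 lists large enough for camera, 5 were called in GMB1 against control and 0 were when the correlation between genes was estimated (smallest adjusted p 0.122). For these 5 fry gave p from 0.000329 (diterpenoid phytoalexin synthesis) to 0.0811 (cell wall genes). In replicates 2 and 3, without control replicate 1 and without GMB1 replicate 3, 8 lists were called, the same 3 being added each time: pathogenesis-related proteins lower (adjusted p 0.00745, 0.00116 and 0.0021), histones and cell cycle genes higher (0.00726, 0.000771 and 0.00233) and cytosolic ribosomal proteins higher (0.00599, 0.000407 and 0.0193). The first was also called with the replicate block (0.0102), and ribosomal proteins after quantile normalization (2.4e-05). Over all arrays the histone genes H2B.5, H2B.6, H2B.7, H2B.10, H2B.11 and CenH3 were at −0.11, −0.12, −0.01, −0.05, −0.25 and −0.22 under GMB1. The lists not called, with their camera adjusted p, were pathogenesis-related proteins (14 genes, 0 called, 2 over the list alone, 0.067), histones and cell cycle (31 genes, 0 called, 0.0617), ribosomal proteins (23 genes, 0 called, 0.106), protease inhibitors (7 genes, 0 called, 0.124) and KNOX genes (9 genes, 0 called by the probe set used for the list, 4 over the list alone, 0.124; called higher at 0.0443 without probe sets shared between genes). Those further from the threshold were salicylate-linked regulators (9 genes, NH1 called, 0.261), gibberellin and cytokinin genes (30 genes, CKX3 and RR1 called, 0.261), auxin genes (56 genes, ARF16 called, 0.364) and ethylene genes (9 genes, 0 called, 0.54). Photosynthesis genes (9 genes, 0 called, 0.541), lipid transfer, wax and cuticle genes (6 genes, 0 called, 0.541), phenylpropanoid genes (30 genes, CAD8A called, 0.826), heat shock proteins (41 genes, HSP18.6 called, 0.826), nitrogen supply genes (9 genes, 0 called, 0.826), sugar and starch genes (40 genes, 0 called, 0.875) and antioxidant enzymes (18 genes, GST-I called, 0.947) were not called either. Flavonoid synthesis, class III peroxidases and seed storage proteins had 2, 3 and 4 tested genes, too few for camera, with 0 called. The list of resistance gene receptors had 0 tested members.

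The second comparison, GMB4M against control, asks the same of the biotype that overcomes the resistance. Here 436 probe sets were called, 246 higher and 190 lower in GMB4M (56.4% higher), with log2 changes up to 5.52 and down to −5.02. All 436 had no overlap between the 3 and 3 arrays, which held for 17.98% of all tested probe sets against 10% by chance. The median over tested probe sets was −0.07, and after median centring it was 0.18, with 84.3% of 1823 calls higher. With replicate number as a block 2340 were called, 980 higher and 1360 lower (41.9% higher), and with replicates 2 and 3 alone 5389, of which 71.4% were higher. The majority direction therefore depends on the setting. These calls kept 436 and 429 of the 436. Without control replicates 1, 2 and 3 in turn the count was 1610, 131 and 76, and without GMB4M replicates 1, 2 and 3 it was 701, 155 and 25.

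Diterpenoid phytoalexin genes were lower in 12 of 12 under GMB4M too, by −1.62 relative to all genes (adjusted p 3.8e-09, but 0.199 with an estimated correlation; −1.45 within replicate 1, −1.81 within replicates 2 and 3). CPS4 at −2.31 (SE 0.47, adjusted p 0.0334), CYP99A2 at −1.91 (SE 0.36, adjusted p 0.0248), CYP99A3 at −1.86 and KSL7 at −1.70 were called, and 9 genes were called over the list alone. In jasmonate synthesis and signalling 29 of 35 were lower (−0.46, adjusted p 4.8e-06, but 0.676 with an estimated correlation; −0.66 within replicate 1, −0.26 within replicates 2 and 3), with 6 called and 13 over the list alone, all lower. CM-LOX1 changed by −2.89 (SE 0.31, adjusted p 0.00201), CM-LOX2 by −2.53 (SE 0.44, adjusted p 0.0154), OPR6 (LOC4340484) by −2.29 (SE 0.45, adjusted p 0.0268), OPR-1 by −2.14 (SE 0.45, adjusted p 0.0366; other probe set −2.01, not called), the jasmonate-responsive JAMYB by −1.78 (SE 0.39, adjusted p 0.0430) and AOS2 by −1.30 (SE 0.29, adjusted p 0.0492).

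Pathogenesis-related proteins and WRKY transcription factors had 0 called genes but were called as lists at the preset correlation, and not with an estimated one (adjusted p 0.676 each). Pathogenesis-related proteins were lower in 11 of 14 genes (−0.75, adjusted p 0.00473), with 5 called over the list alone; within replicate 1 the shift was −0.06 and within replicates 2 and 3 it was −0.92. WRKY factors were lower in 5 of 6 (−0.76, adjusted p 0.0159), with 3 called over the list alone, at −0.13 within replicate 1 and −0.90 within replicates 2 and 3. Both calls ended without GMB4M replicate 3, at adjusted p 0.0878 and 0.132. NH1 fell by 0.98 (SE 0.22, adjusted p 0.0474).

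The cell wall, histone and ribosomal lists were called higher under GMB4M at the preset correlation, and not with an estimated one (adjusted p 0.676, 0.78 and 0.895). Cell wall loosening and synthesis was higher in 40 of 51 genes (0.47, adjusted p 5.0e-05; 0.29 within replicate 1, 0.53 within replicates 2 and 3). The expansin genes EXP29 at 1.94 (SE 0.26, adjusted p 0.00656), EXLA4 at 1.84 (SE 0.27, adjusted p 0.00945) and EXPB3 at 1.29 (SE 0.29, adjusted p 0.0492) were called, and 9 over the list alone. Histones and cell cycle genes, which mark dividing cells, were higher in 24 of 31 (0.49, adjusted p 0.000724, with 0.08 within replicate 1 and 0.64 within replicates 2 and 3). The cyclin gene CYCD3-2 was called at 1.24 (SE 0.25, adjusted p 0.0339) and 4 genes over the list alone. The histone genes of the list did not share this rise. H2B.5, H2B.6, H2B.10 and H2B.11 were at −0.11, −0.11, −0.35 and −0.23, H2B.7 at 0.02 and CenH3 at 0.04. Cytosolic ribosomal proteins were higher in 19 of 23 with 0 called (0.26, adjusted p 0.0110; 0.14 within replicate 1, 0.38 within replicates 2 and 3), a call that ended without control replicate 3 (adjusted p 0.231) and without GMB4M replicate 1 (0.0818). The KNOX gene HOS9 rose by 1.35 (SE 0.25, adjusted p 0.0216). OSH1 rose by 1.49 (SE 0.25, adjusted p 0.0142) on the probe set that had given 1.16 under GMB1, and by 1.40 (adjusted p 0.0623, not called) on the one that had given 1.74. In the KNOX list 4 were called over the list alone. Its median of −0.26 and mean of 0.29, not set relative to all genes, had opposite signs, and the list was not called (adjusted p 0.335).

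LEA proteins and dehydrins were higher in 7 of 8 genes (0.66, adjusted p 0.0159, but 0.676 with an estimated correlation; 1.48 within replicate 1, 0.63 within replicates 2 and 3), with 0 called and 2 over the list alone. This call ended after quantile normalization (adjusted p 0.185), after median centring (0.352), in replicates 2 and 3 (0.269), without control replicate 1 (0.0644) and without GMB4M replicate 1 (0.38).

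Single genes repeated several of the GMB1 changes. MEL1 rose by 4.47 (SE 0.47, adjusted p 0.00180), to a mean signal of 653, MADS18 by 3.09 (SE 0.30, adjusted p 0.00180; 2185) and OsPIP2;4 by 2.84 (SE 0.30, adjusted p 0.00180; 2558). The tonoplast aquaporin gene OsTIP2;1 rose by 3.35 (SE 0.43, adjusted p 0.00565; 23.3 to 238) and OsPIP2;5 by 2.58 (SE 0.43, adjusted p 0.0130). CKX3 rose by at least 2.05 (fitted 2.87), RR1 by 1.64, ARF16 by 1.89, GST-I by 1.24, and IAA7, an auxin repressor gene, by 1.93 (SE 0.36, adjusted p 0.0222). The sugar transporter gene SWEET15 rose by at least 2.60 (fitted 3.55, SE 0.77, adjusted p 0.0430; 12.9, below the median of every control array, to 152) and the wax synthesis gene KCS20 by 1.40 (SE 0.25, adjusted p 0.0172). The starch synthase gene SSII-3 rose by 2.33 (SE 0.41, adjusted p 0.0162) through 1 probe set, the other giving 0.19. Among the named genes that fell, CPDK2 changed most, at −3.20 (SE 0.67, adjusted p 0.0363; 2317 to 253). GLP2 changed by −2.96 (SE 0.38), CIPK10, a calcineurin B-like interacting kinase gene, by −1.96 (SE 0.43) through 1 of its 4 probe sets, the others not being called (adjusted p 0.0773 to 0.0886), the metallothionein gene MT-1-4b by −1.94 (SE 0.42), CAD8A by −1.77 (SE 0.39) and cap2 from a mean signal of 1434 to 239. The catalase gene CAT-A fell by 1.14 (SE 0.25, adjusted p 0.0486) through 1 of its 3 probe sets.

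**Figure D1:**
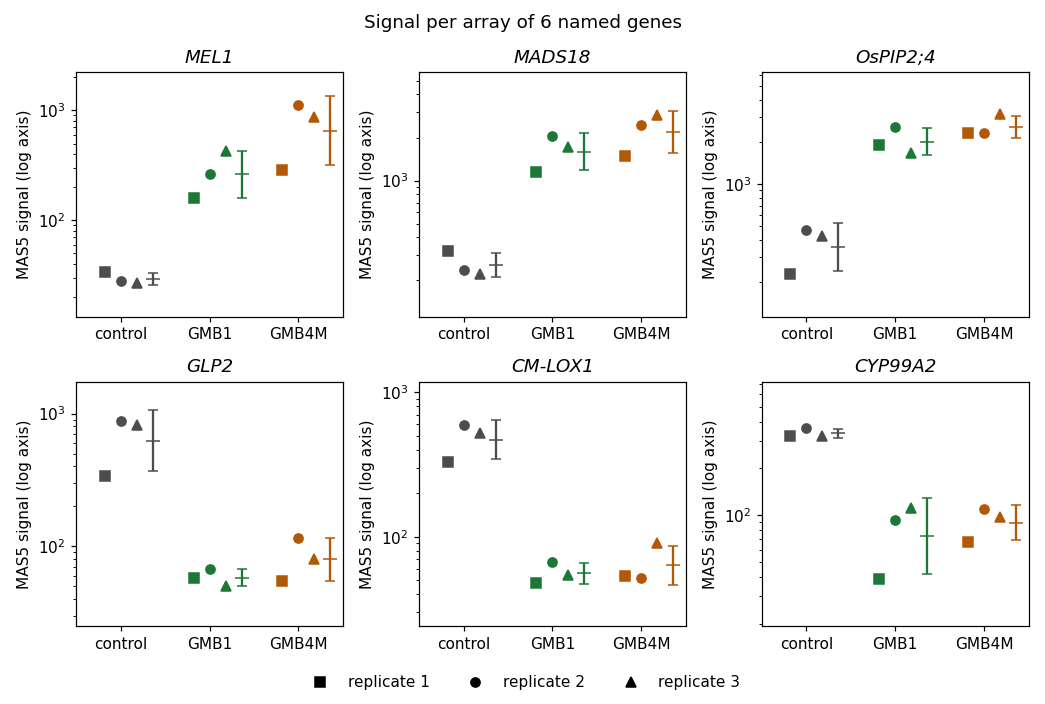
Array signal on a log axis for 6 genes in the control, GMB1 and GMB4M groups; squares, circles and triangles are replicates 1, 2 and 3, and the capped bar is the geometric mean ± 1 SD on the log2 scale (n = 3). MEL1 and MADS18 arrays of both infested groups lie above all control arrays, and CM-LOX1 arrays lie below them.

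Heat shock proteins held more calls over all probe sets than any other list under GMB4M. Over the list alone jasmonate genes held more, 13 against 11. Of 41 tested heat shock genes 7 were called, all higher: HSP16.9A at 3.47 (SE 0.59, adjusted p 0.0154), HSP23.2 at 3.28 (SE 0.63, adjusted p 0.0247), HSP16.9B (LOC4325698) at 2.95 (SE 0.59, adjusted p 0.0297), HSP18.6 at 1.89, CLPB1 at 1.84, HSP18.0 at 1.76 and HSP26.2 at 1.72. The HSP18.6 value is from the probe set that gave 1.59 under GMB1; the one that gave 1.77 there was at 2.38. The other probe sets of HSP18.0 gave −0.12 and 0.19. Over the list alone 9 were higher and 2 lower. The list also holds heat stress transcription factor genes, and the 7 called are not among these. Both lower genes are such factors, HSF6 at −0.97 and HSF03 at −1.83, as is HSF2 at 0.96 among the 9 higher. The list's median and mean therefore mix both kinds of gene. The list as a whole was not called (median 0.02 and mean 0.31, not set relative to all genes, adjusted p 0.159). With the replicate block it was called, at 0.0035, and without control replicate 2, at 0.0407. The rise was uneven between arrays: HSP16.9A signal was 519, 3152 and 3929 in GMB4M replicates 1, 2 and 3, against 175, 187 and 143 in control.

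In GMB4M against control 8 of 21 lists were called and 0 with an estimated correlation (smallest adjusted p 0.199). For these 8 fry gave p from 0.000527 (diterpenoid phytoalexin synthesis) to 0.28 (cytosolic ribosomal proteins). Beside the KNOX and heat shock lists, those not called were salicylate-linked regulators (NH1 called, adjusted p 0.113; called lower at 0.0247 without probe sets shared between genes), protease inhibitors (0 called, 0.157), phenylpropanoid genes (CAD8A called, 0.172), ethylene genes (0 called, 0.433) and gibberellin and cytokinin genes (CKX3 and RR1 called, 0.685). Nitrogen supply (0 called, 0.685), sugar and starch genes (SWEET15 and SSII-3 called, 0.853) and auxin genes (ARF16 and IAA7 higher, GH3-2 lower at −1.63, 0.853) were not called. Antioxidant enzymes (GST-I called by the probe set used for the list, 0.992), photosynthesis genes (0 called, 0.992) and lipid transfer, wax and cuticle genes (KCS20 called, 0.992) were not called. The 3 lists too small for camera had 0 called. Over the 3 comparisons, 25 of 72 list results differed in sign between median, mean and test, and 0 of the 19 called ones did.

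For the 26 genes named under GMB1 and the 34 under GMB4M, all calls held under the block and in replicates 2 and 3, and 0 changed sign in any setting tried. Calls were lost when a single array was left out: for GMB1, 19 without control replicate 2, 20 without control replicate 3, and 17, 12 and 9 without GMB1 replicates 1, 2 and 3. For GMB4M, 20 were lost without control replicate 2, 24 without control replicate 3, and 8, 20 and 30 without GMB4M replicates 1, 2 and 3; without control replicate 1 the loss was 0 in both.

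The responses to the biotypes were then compared with each other. Across 30410 probe sets the log2 changes under GMB1 and GMB4M correlated at 0.81, and 81.1% had the same sign; probe sets are not independent replicates. Both comparisons share the 3 control arrays. In 100 simulations of 2 unchanged groups against 1 shared control group, with no replicate effect common to the groups, the correlation was 0.50 (0.477 to 0.525) and the same-sign share 66.6%. The covariance was 0.288 against 0.102 in the simulations, a difference of 0.186. Effects that arrays of the same replicate number share are not in that simulated level. In replicates 2 and 3 the correlation was 0.83. Of the called probe sets 205 were shared, 100 higher and 105 lower in both, with 0 in opposite directions; independent lists would share 0.93 and 0.89, which leaves out the shared controls. The simulations shared 0, but unchanged groups give hardly any calls, so this sets no level. A further 52 were called only in GMB1 and 231 only in GMB4M, which does not show that they differ between biotypes. The 3 controls cannot be split into parts of at least 2 arrays, so part of the excess may come from the shared controls or from shared replicate effects.

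**Figure D2:**
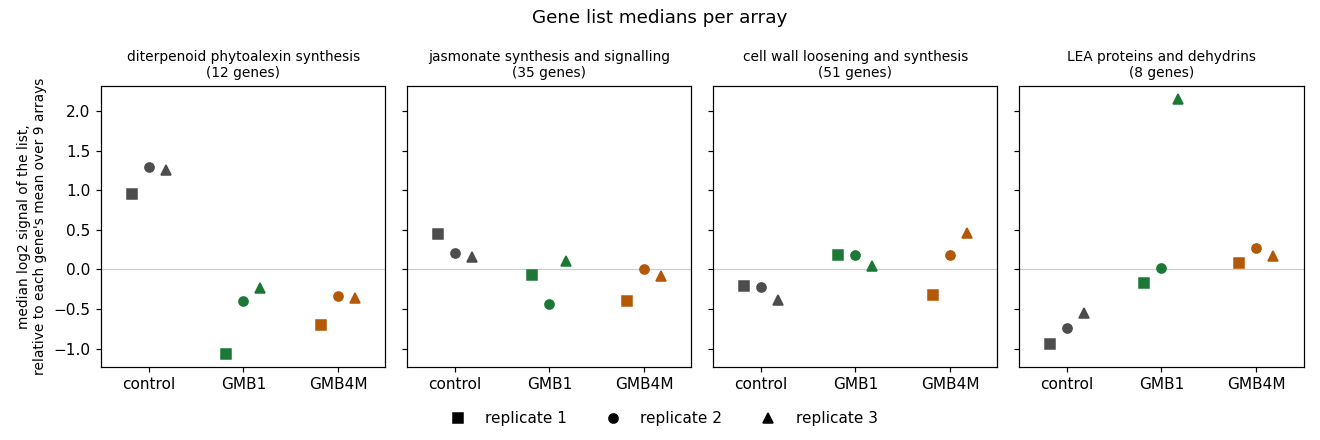
Median per array of the log2 signal of a gene list, each gene set to its mean over the 9 arrays, for the 3 groups, with 1 point per array. Diterpenoid phytoalexin genes lie lower in all infested than in all control arrays, and GMB1 replicate 3 lies apart in LEA proteins and dehydrins at 2.16.

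The third comparison, GMB4M against GMB1, asks what separates the virulent from the avirulent biotype. With limma 0 of 30410 probe sets passed (smallest adjusted p 1.00). An unadjusted p under 0.05 was found for 543 (1.79%), a smaller share than chance would give at that threshold. Groups did not overlap in 5.74% against 10% by chance. Both shares lie below their chance level, so 0 calls do not show that differences are few. In replicates 2 and 3 alone 31 probe sets were called, 23 higher and 8 lower in GMB4M. Without GMB4M replicate 1 there were 4, which, chosen for naming after their values were seen, were HSP16.9B (LOC4325698) at 3.55, HSP23.2 at 3.68, HSP16.9A at 3.32 and LOC4347408 at −3.09. Each of the other 5 infested arrays left out gave 0.

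None of the genes named for this comparison passed; they have the smallest unadjusted p in each direction among probe sets of 1 gene with a name other than a LOC number and a higher group mean above the 75th percentile. All had an adjusted p of 1 in limma. Higher in GMB4M were HSP26.7 at 2.71 (SE 0.56, p 0.000358), HSP16.9B (LOC4325698) at 2.61 (SE 0.59, p 0.000727), HSP23.2 at 2.69 (SE 0.63, p 0.000961), HSP16.9A at 2.40 (SE 0.59, p 0.0015) and HSP18.0 at 1.52 (SE 0.38, p 0.00164; its other probe sets gave 0.01 and 0.16), followed by the cell wall invertase gene CIN2 at 0.88, the growth-regulating factor gene GRF8 at 0.84 and CLPB1 at 0.92. Lower in GMB4M were the heat stress factor gene HSF1 at −0.93 (SE 0.30, p 0.00941; other probe set −0.20) and the pyruvate decarboxylase gene PDC1 at −2.12 (SE 0.83, p 0.0243). PDC1 signal was 1584, 129 and 108 in GMB4M replicates 1, 2 and 3, and 484, 1673 and 2252 in GMB1, so replicate 1 went the other way. The remaining 6 were CPDK2 at −1.21, OPR1 at −0.80, rbcS at −0.79, JAMYB at −0.73, IAA19 at −0.55 and BHLH175 at −0.45, with unadjusted p from 0.0558 to 0.109. Other probe sets gave −0.16 and −0.67 for rbcS and 0.08, of opposite sign, for BHLH175.

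**Figure D3:**
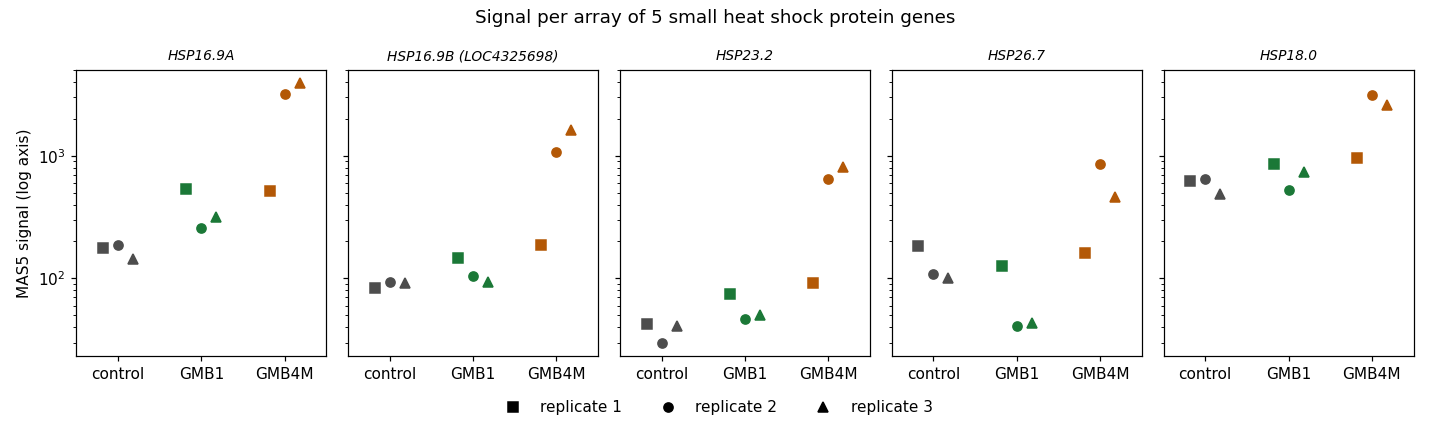
Signal per array on a log axis of 5 small heat shock protein genes in control, GMB1 and GMB4M, with 1 point per array. GMB4M replicates 2 and 3 lie above the other arrays, as for HSP16.9A at 3152 and 3929 against 519 in GMB4M replicate 1.

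Of the 21 lists 6 were called between the biotypes, and 0 with an estimated correlation (adjusted p 0.945 for each). Higher in GMB4M were histones and cell cycle genes (28 of 31 higher, 0.24 relative to all genes, adjusted p 0.00154; 0.04 within replicate 1, 0.28 within replicates 2 and 3) and heat shock proteins (31 of 41 higher, median 0.04 relative to all genes, adjusted p 0.00212; 0.07 within replicate 1, 0.10 within replicates 2 and 3; 6 genes called over the list alone). In the histone and cell cycle list, the histone genes H2B.5, H2B.6, H2B.7 and H2B.11 were at 0.005, 0.008, 0.03 and 0.02, H2B.10 at −0.29 and CenH3 at 0.26. The mean of the heat shock list, 0.33 relative to all genes, was larger than its median. Both values include the heat stress transcription factor genes of that list. Lower were LEA proteins and dehydrins (8 of 8 lower, −0.48, adjusted p 0.00154), phenylpropanoid genes (21 of 30 lower, −0.14, adjusted p 0.0205), jasmonate genes (21 of 35 lower, −0.14, adjusted p 0.0261) and pathogenesis-related proteins (8 of 14 lower, −0.14, adjusted p 0.0497). The LEA shift was 0.60 within replicate 1 and −0.93 within replicates 2 and 3, and that of pathogenesis-related proteins 0.07 and −0.35, so the direction of both did not hold within replicate 1. Phenylpropanoid genes gave −0.16 and −0.10, and jasmonate genes −0.21 and −0.09. Without GMB1 replicate 3 a single list was called, and the signs of the LEA and pathogenesis-related lists turned (adjusted p 0.532 and 0.745). Without GMB4M replicate 3 there were 3 called lists.

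Of the other lists between the biotypes, ribosomal proteins came nearest (22 of 23 higher, adjusted p 0.0632) and were called without GMB1 replicate 1 (0.00509) and without GMB4M replicate 2 (0.0137). Photosynthesis genes (0.234, called lower at 0.0108 without GMB4M replicate 1), salicylate-linked regulators (0.323), auxin genes (0.323), gibberellin and cytokinin genes (0.323) and diterpenoid phytoalexin genes (0.426) were not called. The diterpenoid list was at 0.23 relative to all genes, with 0.67 within replicate 1 and −0.16 within replicates 2 and 3, where it was called lower in GMB4M (adjusted p 0.0291). Nor were lipid transfer, wax and cuticle genes (0.523), cell wall genes (0.524), and ethylene, WRKY, sugar and nitrogen genes (0.629 each). KNOX genes (0.801), protease inhibitors (0.887) and antioxidant enzymes (0.939) were furthest from the threshold.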

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

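The tests of the phytoalexin and heat shock patterns were chosen after their results were seen; the test of the absent calls between biotypes and the splits of the arrays were set before. The heat shock tests were changed several times after their results were seen. On the list median, 0.04 relative to all genes before any correction and so below the bound of 0.1, they decided nothing. On the list mean, the value left after quantile normalization (0.323) lay above 0.1 by less than 2 standard errors. The part of the mean relative to all genes that the normalization removes had argued against scale, but it is nearly fixed, since no list moved by more than 0.104, so the mean is now taken without setting it relative to other genes. The batch tests of both patterns first asked for the difference within replicate 1 as well, which has 1 array per group, and for heat shock genes had met what a batch requires; they now leave replicate 1 out.

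A direct test of the difference between the infested groups set 6 gene lists apart, by camera with a preset correlation. Higher in GMB4M than in GMB1 were histones and cell cycle genes (adjusted p 0.00154, 28 of 31 genes higher, median log2 change 0.30) and heat shock proteins (0.00212, 31 of 41, 0.11). Lower were LEA proteins and dehydrins (0.00154, 8 of 8 genes lower, −0.42), phenylpropanoid and lignin synthesis (0.0205, 21 of 30, −0.08), jasmonate synthesis and signalling (0.0261, 21 of 35, −0.08) and pathogenesis-related proteins (0.0497, 8 of 14, −0.07). The medians of these 6 lists are not set relative to all genes here. With an estimated correlation all 6 had an adjusted p of 0.945. Fry gave p from 0.30 (histones and cell cycle) to 0.80 (jasmonate genes) for the 6. Each lost its call without at least 1 of the 6 infested arrays. Histones did so without GMB1 replicate 3 (0.499) and GMB4M replicate 1 (0.242), and heat shock proteins without GMB1 replicate 2 (0.137). LEA proteins did so without GMB1 replicate 3 (0.532, direction turned) and GMB4M replicate 3 (0.324), and phenylpropanoid genes without GMB1 replicate 3 (0.388) and GMB4M replicate 1 (0.0902). Jasmonate genes did so without GMB1 replicate 1 (0.154), GMB1 replicate 3 (0.91) and GMB4M replicate 3 (0.671), and pathogenesis-related proteins without GMB1 replicate 3 (0.745, direction turned) and GMB4M replicate 3 (0.671).

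Diterpenoid phytoalexin genes were lower in both infested groups, with 7 of 12 genes called under GMB1 and 4 of 12 under GMB4M. Camera called the list at the preset correlation and not with an estimated one (adjusted p 0.122 and 0.199). Fry gave p of 0.000329 under GMB1 and 0.000527 under GMB4M. A difference in scale between arrays is argued against: after quantile normalization the list median, not set relative to other genes, was −1.61 in the comparison nearer 0 (jackknife standard error over arrays 0.144). An effect equal on the log2 scale in all replicate 1 arrays cancels in these comparisons, so leaving them out does not test it. The fall did not rest on those arrays: without replicate 1 the median relative to all genes was −1.70 in the comparison nearer 0 (0.116). For a smaller share of green tissue, the rule asked that photosynthesis genes fall by at least 50% of the phytoalexin change in both comparisons. This rule was written after the result. Photosynthesis genes were at 0.26 relative to all genes in GMB1 and at 0.016 in GMB4M. The spread in GMB1 was 0.361, the larger of the jackknife standard error over arrays and the standard error over genes. None of the 9 photosynthesis genes is in another list. Within replicates 2 and 3 they were at −0.19 in GMB1 and −0.32 in GMB4M, against −1.70 and −1.81 for the phytoalexin list. The harvest time of the controls, which the labels do not give, coincides with infestation and stays open as untested, as does a response of the plant to infestation. Ribosomal RNA and Bacillus spike signals were higher in every control array than in every infested array. Whatever caused that also coincides with infestation, and its part in this pattern was not tested. Lower phytoalexin gene expression under both biotypes may reflect any of these.

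The heat shock list was called higher in GMB4M than in GMB1 at the preset correlation and not with an estimated one (adjusted p 0.945), with 0 genes called by limma and a list median of 0.04 relative to all genes. Quantile normalization removed 0.0518 (jackknife standard error 0.184) of a list mean of 0.385. The error is too large to place this below 50% of the mean, so a difference in scale between arrays stays open. The list stayed called under that normalization (adjusted p 0.0326) and not after median centring (0.0517), which leaves the mean relative to all genes at 0.327; why was not tested. An effect equal on the log2 scale in all replicate 1 arrays cancels between the groups, so leaving them out does not test it. The low value within replicate 1 was also known before this test was set, so its outcome is not counted against a batch. The difference did not rest on replicate 1: without it the mean relative to all genes was 0.457 (0.163). Within replicate 1 it was 0.0668 on 1 array per group, which has no spread, so whether replicate 1 shares the difference is not known. A difference between the biotypes in what they do to the plant stays open as untested, and so does a difference in handling of GMB4M replicates 2 and 3.

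No probe set was called between GMB4M and GMB1 by limma, with 543 (1.79%) at an unadjusted p under 0.05. That share is smaller than chance would give at this threshold. With the replicate 1 arrays left out and quantile normalization 11 were called, between the 10 that would have argued against the batch as the cause and the more than 100 it would need, so whether it hid differences cannot be told apart from there being few. Under the other settings tried the count was 0, except for 31 in replicates 2 and 3 without normalization, 8 under the block, 4 without GMB4M replicate 1 and 5009 under arrayWeights.

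Splits of the 6 arrays of a comparison number 10, too few for a share under 0.05. For GMB1 against control the real split called 257 and the highest of the others 0 (1 of 10 as large); for GMB4M against control 436 and 0 (1 of 10); for GMB4M against GMB1 0 and 0 (10 of 10).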

How the results depend on the processing

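The batch term, replicates 2 and 3 alone, median centring over tested probe sets and the joint settings were chosen after seeing the data. Values follow in the order GMB1 against control (257 calls), GMB4M against control (436) and, where it moved, GMB4M against GMB1 (0).

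Calls moved by more than 1.5 times under quantile normalization (673, 1584), median centring (449, 1823), median centring over tested probe sets (557, 1454), no filter (112, 256; more probe sets tested), eBayes without trend (44, 219) and fits of only the groups compared (121 in GMB1; fewer arrays). They rose under the replicate block (1471, 2340, 8), a replicate 1 batch term (1551, 2509), replicates 2 and 3 alone (2503, 5389, 31), quantile normalization with the batch term (2912, 4963) and with replicates 2 and 3 alone (3277, 5586, 11). Under arrayWeights they were 4249, 13738 and 5009, but its iteration stopped before convergence with weights from 0.129 to 36.8 (GMB4M replicate 2). Leaving out each array gave 31 to 729, 25 to 1610 and 0 to 4. Beyond the settings whose construction is named, the cause was not tested. The offset of 32, the 60th percentile filter, robust eBayes and leaving out shared probe sets stayed within 1.5 times. No probe set call took the opposite sign in any setting. Of the 26 and 34 named genes, 11 and 14 lost their call with no filter, 21 and 19 without the trend and 13 and 6 with only the groups compared, and 0 reversed.

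Over all groups 5 of 9 arrays were best matched outside their group by their own number, a hint from the data only. For GMB4M against GMB1 the numbers were not taken as pairs. The block called 8, among them HSP26.7, HSP16.9B (LOC4325698) and HSP23.2, and ended 2 list calls there, pathogenesis-related proteins (0.0814) and phenylpropanoid genes (0.0583). In the comparisons with control it ended no call of a list or named gene and added 1 list in each, pathogenesis-related proteins in GMB1 (0.0102) and heat shock proteins in GMB4M (0.0035).

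Lists called (5, 8 and 6) fell to 0, 0 and 0 with the estimated correlation. They were 8 in GMB1 in replicates 2 and 3, and 3 between biotypes under quantile normalization and under no filter. Leaving out each array gave 4 to 8, 6 to 9 and 1 to 7. Between biotypes without GMB1 replicate 3, the pathogenesis-related and LEA lists reversed (adjusted p 0.745 and 0.532); leaving out other infested arrays gave p as low as 0.000526 (without GMB1 replicate 1) and 1.6e-06 (without GMB1 replicate 2). The cause was not tested.

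The correlation of the responses (0.81) was 0.604 with no filter and 0.886 with the stricter one, where weak probe sets were added or removed, and 0.729 to 0.876 without each array. Signal near background limits what the unfiltered probe sets can show.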

Other observations

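The aquaporin family was picked and tested after its values were seen. Of 22 tested aquaporin genes 4 were called higher under GMB1 (OsTIP2;1 at 2.61, OsPIP2;4 at 2.49, OsPIP1;3 at 2.08 and Lsi6 at 1.92) and 5 under GMB4M, which adds OsPIP2;5; 0 were called lower in either. Among 16086 genes 78 and 173 were called higher, and a 1-sided Fisher's exact test gave p of 3.5e-06 and 3.1e-06; the family was chosen for these genes, so the p is not independent evidence. Of the whole family 12 of 22 were higher in each comparison, with a median relative to all genes of 0.26 and 0.09, and 0.28 and 0.13 after quantile normalization. Camera gave an unadjusted p of 0.00155 and 0.0174 for a shift up at the preset correlation, and 0.195 and 0.315 with an estimated one; this too is on a family picked for its values. Within replicate 1 it was 0.36 and 0.12, and within replicates 2 and 3 it was 0.14 and −0.03, the last of opposite sign. Between GMB4M and GMB1 0 were called.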
